A study of Arabidopsis thaliana with 51 samples.

How the data were processed

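Transcript levels were measured on 51 two-colour arrays of 27648 probes each. On 45 arrays RNA of an Arabidopsis organ was set against RNA of cultured cells, and on 6 arrays RNA of an organ in light was set against RNA of the same organ in the dark. Arrays were grouped by the organ and condition in their labels, giving 20 groups of 2 to 4 arrays. The labels 1DBP, 1DPP, 3DPP and 8DPP are used as they stand, since the sources used here do not spell them out. The deposited values are log2 ratios of the RNAs on an array, down to a ratio of 0.001. All values below -1 were the log2 of whole thousandths, within 0.01 of a thousandth, and higher values were not checked for this. How the authors took the images, subtracted background and normalized is not given in the sources used here, and signal over background was not analysed here. Array medians ran from -0.60 to 1.06, so the deposited values are not centred per array. An array held between 7410 and 26657 values.

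The organ was labelled in channel 1 on the rosette leaf, cauline leaf and stem arrays and on 1 of the 2 light root arrays. On the other arrays against cultured cells it was in channel 2, so dye and organ are confounded there except in light roots. On the direct arrays the light RNA was in channel 1 for cotyledons and roots, and in channel 2 for hypocotyls. The 2 light root arrays, with the organ in opposite channels, correlated at 0.75 over 25305 probes. The deposited ratios were therefore read as organ over cultured cells in both orientations. Both of these arrays carry the number 1 in their labels, which do not say that their RNA was separate. The lowest correlation between any 2 arrays against cultured cells was 0.295. That the whole table runs organ over reference and light over dark is likely, not known, and rests on photosynthesis genes being higher in light cotyledons. The direct hypocotyl arrays are given as deposited, with no direction.

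Gene names came from the annotation table of the probes. It names 2676 probes, of which 2032 carry 1 gene symbol and 644 several. Of the 2032, 2029 matched a gene of the RefSeq annotation TAIR10.1 by Entrez identifier, used for names alone. The 182 probes whose accession is a genomic clone were left unnamed, since probes sharing such an accession correlated at a median of 0.233, against 0.766 for the accessions kept, and so were 7 probes that disagreed with others of their accession. The 3 control accessions with 17 spots each were averaged, leaving 27600 features, called probes in the text, of which 1795 name 1751 genes. All other probes count in the numbers of calls but are not named.

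Each array was centred on its median. A moderated fit with 1 mean per group over all 51 arrays, with the variance moderation of limma 3.58.1 in R 4.3.3, gave log2 changes, standard errors and two-sided p-values, adjusted by the Benjamini-Hochberg method within each comparison. A probe was tested with at least 2 values in every group compared, and called at an adjusted p under 0.05 and at least 2-fold. The 37 comparisons were each organ group against cultured cells, the direct light arrays, differences between related organs, light against dark through the reference, and 2 differences between light responses. Groups and comparisons, thresholds, lists and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 8 highest and 8 lowest called genes, and the 3 largest called members of each list with at least 3 called. The highest and lowest had to lie on the same side of the second group's mean, or of 0, in every array of the first group. Arrays of the second group were not checked for this. The text gives the larger of the genes so named. Genes of lists with 3 or fewer measured members are given as the result of their list. The values of VGD1 and ACT12 in pistils, petals and sepals were chosen after they were seen.

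Of 21 gene lists drawn up before the data were examined, 12 had a measured gene: photosynthesis (8), chlorophyll synthesis (3), pollen (3), cell cycle (2), pistil and ovule regulators (2), seed storage (2), glucosinolate synthesis (2), heat shock (2), endosperm and seed coat (1), fatty acid β-oxidation (1), root (1) and expansins (1). A further 8 were added once gene names, but no comparison, had been seen: peroxidases (24), glycosyl and glutathione transferases (14), ubiquitin proteases and conjugating enzymes (13), tubulins and actins (9), dehydration, cold and late embryogenesis genes (9), DNA recombination and repair (9), β-glucosidases (8) and thylakoid and photorespiration genes (7). Lists with at least 3 measured genes were tested against the other named genes with limma's camera, at its preset correlation of 0.01 and at one estimated from residuals, adjusted over the lists of a comparison. List counts are also given adjusted over the list alone.

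Alternatives were no centring, scaling between arrays to a common median absolute value (limma's normalizeMedianAbsValues, separately for arrays against cultured cells and direct arrays), probes with a value on every array compared, a fit on the groups compared alone, leaving out each array, the array number as a block, direct and reference arrays in 1 fit, a single orientation of the light root arrays, and removal of the dye difference seen between these. Centring on named probes, and the combined fit with the direct hypocotyl arrays turned, were chosen after seeing the data. Other splits of the arrays were run for comparisons of at least 3 arrays per group, up to 100 with seed 20240. The fit was tested on simulated data by adding known log2 changes of 1.5 and 3 to 100 probes each. Noise was independent and normal, with the spread the fit estimated for each probe, equal in all groups. At 1.5 the fit recovered 33 for direct cotyledons, 16 between leaves, 28 between pistils and 43 between siliques. At 3 it recovered 84, 67, 71 and 69, with 5 to 9 false calls. Real groups differed in spread, with a median root mean square difference between arrays from 0.75 in sepals to 1.57 in petals. The false calls therefore do not test the assumption of equal spread. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.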

Results

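The series measured transcript levels in organs of Arabidopsis thaliana, the thale cress, on 51 two-colour arrays, each carrying 27648 probes. On 45 arrays the RNA of an organ was set against RNA of cultured cells, a reference common to 17 organ groups. The groups of 2 arrays were light cotyledon, light hypocotyl, dark hypocotyl, light root, dark root, sepal and the pistil labelled 1DBP. The groups of 3 were dark cotyledon, germinating seed, rosette leaf, cauline leaf, stem, petal, stamen and the siliques labelled 3DPP and 8DPP, and the pistil labelled 1DPP had 4. A further 6 arrays set light directly against dark, with 2 each for cotyledon, hypocotyl and root. An array held between 7410 and 26657 values, the fewest on replicate 3 of the silique 8DPP group, and the light hypocotyl arrays held 19267 and 19326. Correlations across probes between arrays of a group ran from 0.47 for the direct root arrays to 0.94. The number of arrays limits the precision of every value. The labels do not say that replicates came from separate plants or cultures, so p-values measure the spread between these arrays, which may be technical. Values are log2 ratios after each array was centred on its median, errors are standard errors of the limma fit, and n is the number of arrays. Genes named for the size of their change lay on the same side in every array of the first group of the comparison. Most probes carry no gene name here, so that 1751 genes could be named.

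Photosynthesis genes were the group furthest above cultured cells in green organs. In rosette leaves all 7 measured members of the photosynthesis list were higher, with a median of 8.41 and an adjusted p of 3.7e-11, and in cauline leaves all 8 were, with a median of 8.14. LHB1B2, a light-harvesting chlorophyll-binding protein gene, stood at 10.10 ± 0.40 in rosette leaves (n = 3), 8.74 ± 0.40 in cauline leaves, 7.89 ± 0.49 in light cotyledons (n = 2) and 7.02 ± 0.40 in dark cotyledons. PSAN, which encodes a photosystem I subunit, stood at 8.41 ± 0.24 in rosette leaves and 7.83 ± 0.30 in light cotyledons. Leaves and cotyledons had the organ in opposite channels, so a dye effect may add to differences between their levels. The direction of the table was read from photosynthesis genes in light cotyledons (8 of 8 higher, median 7.82), so their sign there is not a finding. With that direction the list was also higher in dark cotyledons (7 of 8, 5.98), stem (7 of 7, 6.32), 3DPP siliques (7 of 7, 5.84), 8DPP siliques (5 of 5, 5.54) and 1DPP pistils (8 of 8, 5.38). Sepals (6 of 8, 4.30), stamens (6 of 8, 4.17), petals (7 of 8, 4.05), light hypocotyls (3 of 3, 3.84) and 1DBP pistils (8 of 8, 3.67) followed. Adjusted over the list alone, these 13 counts were identical. In these groups the list test also passed with an estimated correlation, and no alternative scaling turned a list's direction. The list test missed the threshold in both root groups, dark hypocotyls and germinating seeds. Of the chlorophyll synthesis list 3 genes were measured, PORB, CHLM and GSA1. All 3 were higher in cauline leaves (median 4.96, adjusted p = 0.0025), rosette leaves (4.92), stem (3.58), light cotyledons (3.56), 3DPP siliques (3.38) and dark cotyledons (3.33), also when adjusted over the list alone. Leaving out replicate 1 of the dark cotyledon arrays brought GSA1 there to 0.80, below 2-fold.

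**Figure D1:**
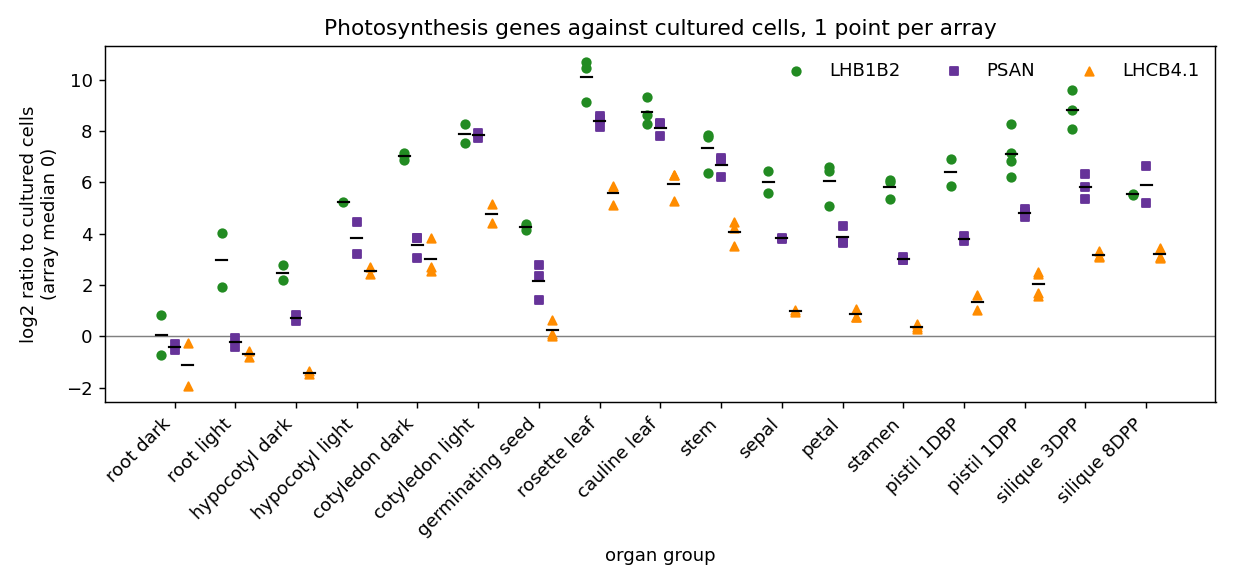
Log2 ratios to cultured cells of 3 photosynthesis genes in the 17 organ groups, with 1 point per array and a black bar at each group mean. LHB1B2 reached a mean of 10.10 in rosette leaves, and PSAN and LHCB4.1 were lowest in the root and dark hypocotyl groups.

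Root arrays were marked by class III peroxidase genes, whose enzymes act on cell walls and in defence. Of 23 measured, 19 were higher than in cultured cells in light roots (median 3.54, adjusted p = 1.7e-09) and 17 in dark roots (3.45, 1.5e-12), with none lower. In dark hypocotyls 15 were higher and 3 lower (2.08, 2.7e-05). AT4G30170 reached 6.81 ± 0.51 in light roots and AT5G17820 6.67 ± 0.46 (n = 2). The RNA on these 2 arrays may be the same, as they carry the same number in opposite channels. The highest named gene in dark roots was AT3G28550, at 7.25 ± 0.42. This list was drawn up after the gene names, though no values, had been seen. In stamens the pollen list stood out, with 3 of 3 genes higher (median 6.42, adjusted p = 0.0017, and adjusted p = 0.033 with an estimated correlation), 3 also when adjusted over the list alone. THI2.1, a thionin gene, was the highest named gene of both pistil groups and of 3DPP siliques, at 9.41 ± 0.73 in 1DBP pistils (n = 2), 10.46 ± 0.52 in 1DPP pistils (n = 4) and 10.24 ± 0.60 in 3DPP siliques (n = 3). INO, a regulator of the outer integument of the ovule, was called in the same 3 groups, at 3.61 ± 0.37, 3.05 ± 0.26 and 3.19 ± 0.30. BAN, an anthocyanidin reductase gene of the seed coat, was higher in 3DPP siliques, at 4.73 ± 0.69, and in 8DPP siliques, at 2.39 ± 0.84.

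Among the smaller lists, EXPB3, the measured expansin gene, stood at 8.50 ± 0.63 in 3DPP siliques and 7.04 ± 0.63 in stem. TOPII and PRL, of the cell cycle list, were highest in pistils and siliques, TOPII at 4.60 ± 0.32 in 1DPP pistils and PRL at 4.15 ± 0.39 in 3DPP siliques. Of the seed storage list, OLEO3 stood at 4.62 ± 0.71 in dark cotyledons and 3.65 ± 0.71 in dark hypocotyls, and AT3G15670 at 2.34 ± 0.46 in dark hypocotyls. The glucosinolate genes UGT74B1 and BCAT4 stood at 2.48 ± 0.29 and 2.38 ± 0.39 in rosette leaves. AIM1 was higher in stamens, at 1.88 ± 0.20, and lower in germinating seeds, at -1.85 ± 0.20. Glycosyl and glutathione transferase genes passed the list test in 10 groups, most clearly in dark roots, where 9 of 12 were higher (median 1.90, adjusted p = 0.00010). Dehydration, cold and late embryogenesis genes passed in 5 groups, with 6 of 9 higher in dark cotyledons (1.44, 0.017). In sepals this list gave 0.043, but adjusted p = 0.070 with an estimated correlation, and missed uncentred (0.052), centred on named probes (0.057) and without sepal replicate 1 (0.062). Thylakoid and photorespiration genes passed in light cotyledons (4 of 7 higher, 5.05, 0.015), rosette leaves (4 of 6, 3.70, 0.025) and cauline leaves (6 of 7, 4.27, 0.031). In cauline leaves they missed without replicate 1 (0.063) or 3 (0.097), and for probes with a value on every array compared (0.062). Tubulin and actin genes passed in 6 groups. Only in stamens (6 of 9, 2.93, 0.0017) did they also pass with an estimated correlation, which gave an adjusted p of 0.070 in dark cotyledons, 0.054 in light hypocotyls, 0.065 in 1DPP pistils, 0.068 in 3DPP siliques and 0.091 in stem. In light hypocotyls 3 lists missed without replicate 1, peroxidases (0.083), tubulins and actins (0.075) and transferases (0.075), and tubulins and actins also without replicate 2 (0.084). In stamens the transferase list missed without replicate 3 (0.058).

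Much the same few genes were lowest in organ after organ. All groups were set against the same cultured cells, so these lows are not separate observations and may reflect high levels in that reference. AT1G19530 stood at -9.84 ± 0.21 in stamens, -9.27 ± 0.21 in petals, -8.99 ± 0.26 in light cotyledons and -7.85 ± 0.26 in light roots, and at -6.15 ± 0.21 in dark cotyledons. AT4G27450 stood at -8.70 ± 0.30 in light cotyledons and -5.34 ± 0.30 in dark roots. The osmotin-like gene OSM34 stood at -9.38 ± 0.26 in germinating seeds and -8.54 ± 0.26 in rosette leaves. Both heat shock genes measured, AT1G53540 and ATHSP22.0, were lower than in cultured cells in all 17 groups. AT1G53540 ranged from -8.37 ± 0.48 in 3DPP siliques to -3.07 ± 0.58 in light hypocotyls, and ATHSP22.0 from -7.54 ± 0.52 in rosette leaves to -3.83 ± 0.52 in stem. LBD16, a lateral root regulator, was lower in 13 groups, down to -4.66 ± 0.55 in 1DBP pistils. The deposited ratios go down to 0.001, and AT1G19530 lay at that limit on all 3 arrays with a value each of rosette leaf, 3DPP silique and 1DPP pistil, on 2 of 3 in cauline leaf and stem and on 1 of 3 in stamen, so its values there are bounds.

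Between 6170 and 13685 probes differed from cultured cells by at least 2-fold at an adjusted p under 0.05. In roots 3321 were higher and 4912 lower in the dark, against 4690 and 3669 in the light. Dark hypocotyls had 4673 higher and 6431 lower, light hypocotyls 3065 and 3105 of only 14978 probes tested, dark cotyledons 5314 and 5535, and light cotyledons 4551 and 5654. Germinating seeds had the most, 6834 higher and 6851 lower. Rosette leaves had 6125 and 4674, cauline leaves 5837 and 4389, and stem 6024 and 4155. In the flower, sepals had 5498 higher and 7187 lower, petals 5764 and 5865, stamens 6187 and 6606, 1DBP pistils 5360 and 4652, and 1DPP pistils 6161 and 5380. Siliques had 6002 and 5030 at 3DPP and 4097 and 4294 at 8DPP. Leaves and stem had the organ in channel 1, and the other groups in channel 2 except on light root replicate p1. Dye and organ are thus confounded in these counts. After centring, the median of named probes ran from 0.04 to 0.25 on arrays with the organ in channel 1. With the organ in channel 2 it ran from -0.42 to -0.10. Tests against 0 also leave out the spread of the reference itself. The balance of higher and lower depended on centring. Without it the higher share of calls went from 49.9% to 73.6% in germinating seeds, 49.7% to 83.9% in light hypocotyls, 48.8% to 78.2% in 8DPP siliques, 49.6% to 74.4% in petals, 53.4% to 72.0% in 1DPP pistils, 48.4% to 67.0% in stamens, 43.3% to 66.4% in sepals, 40.3% to 65.4% in dark roots, 49.0% to 64.9% in dark cotyledons, 42.1% to 60.9% in dark hypocotyls and 44.6% to 55.7% in light cotyledons. With centring on named probes, added after the data were seen, it was 58.5% in stamens, 56.8% in dark hypocotyls, 56.2% in sepals and 51.1% in dark roots. In rosette leaves the higher share fell from 56.7% to 47.4% without centring, so their balance turned. Uncentred, the median of all probes tested lay at 1.12 in germinating seeds, 0.93 in light hypocotyls and -0.29 in rosette leaves. The count for 8DPP siliques fell from 8391 to 2790 without replicate 1 and to 2794 without replicate 2, as replicate 3 has few values, and was 8024 without replicate 3.

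Cauline and rosette leaves, both foliage leaves, differed at 1056 of 25681 probes, 410 higher and 646 lower in cauline leaves. HIS1-3, a linker histone gene, was lowest in cauline relative to rosette leaves, at -6.44 ± 0.79 (adjusted p = 1.8e-06), followed by MCCA, for a methylcrotonyl-CoA carboxylase subunit of leucine degradation, at -4.53 ± 0.38, AT3G07350 at -4.34 ± 0.38, AT4G36850 at -4.15 ± 0.55 and the thionin gene THI2.2 at -4.05 ± 0.75. Scpl25, AT3G11000 and AT1G68660 were highest in cauline leaves, at 5.61 ± 1.21, 4.46 ± 0.84 and 3.64 ± 0.44 (3 arrays per group). No gene list passed its test. Of 16 genes named by the rule, 12 kept their call whichever array was left out. Uncentred, 54.1% of the calls were higher in cauline leaves, against 38.8%. The count was 660 without rosette leaf replicate 3, 661 without cauline leaf replicate 2 and 681 without rosette leaf replicate 2, and a fit on the 6 arrays alone gave 8 calls.

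Stem differed from the mean of both leaf types at 4192 of 25513 probes, 2018 higher and 2174 lower. YAB3, a YABBY gene of abaxial organ identity, lay at -7.19 ± 0.84, AT1G23130 at -7.12 ± 0.50, AT5G44580 at -5.89 ± 0.70 and AT1G76960 at -5.39 ± 0.74. AT5G37940 (6.72 ± 0.73), AT2G45930 (5.12 ± 0.94), AT5G51950 (4.56 ± 0.53), AT5G12120 (3.86 ± 0.59) and the expansin-like gene EXLA2 (3.62 ± 0.48) were highest in stem. Of 7 photosynthesis genes 4 were lower, also when adjusted over the list alone, led by ATPC1 at -2.48 ± 0.55, LHB1B2 at -2.09 ± 0.49 and LHCB4.1 at -1.69 ± 0.31, but the list test gave an adjusted p of 0.080. Of 7 tubulin and actin genes 4 were higher, led by TUB7 at 2.29 ± 0.23 (adjusted p of the list 0.080). TOPII, a topoisomerase II gene, and PRL, both of the cell cycle list, were higher by 1.68 ± 0.46 and 2.03 ± 0.47, as was the β-expansin gene EXPB3, by 2.92 ± 0.77. Leaves and stem all carried the organ in channel 1, so a dye effect cancels here.

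Petals and sepals, the outer organs of the flower, differed at 1784 of 24125 probes, 1229 higher and 555 lower in petals. AT5G11420 (6.19 ± 0.79), AT5G06560 (5.60 ± 0.88), AT3G15450 (3.93 ± 0.36) and AT2G37130 (3.77 ± 0.63), a peroxidase gene, were highest in petals (n = 3 and 2). PIFI was lowest, at -5.74 ± 1.26, followed by AT4G24100 at -4.51 ± 0.85 and the late embryogenesis gene AtLEA4-1 at -3.86 ± 0.73. Of 24 peroxidase genes 3 were higher and none lower, and no list passed its test. Centred on named probes, 57.9% of the calls were higher, against 68.9%. Without sepal replicate 1, PIFI gave an adjusted p of 0.061 and AtLEA4-1 0.17, and without sepal replicate 2, AT4G24100 gave 0.16. The count was 785 without sepal replicate 1 and 636 without sepal replicate 2, and limma on the 5 arrays alone called 0 probes, with 4651 at an unadjusted p under 0.05.

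Stamens, which bear the pollen, differed from the mean of petals and sepals at 1757 of 23881 probes, 1221 higher and 536 lower. All 3 measured pollen genes were higher in stamens: the pollen actin gene ACT12 by 5.29 ± 0.69, VGD1, a pollen pectin methylesterase gene, by 3.65 ± 0.78, and the pollen α-tubulin gene TUA1 by 3.34 ± 0.26 (n = 3 against 5). The list gave an adjusted p of 4.6e-12, and of 4.3e-07 with an estimated correlation, and 3 of 3 when adjusted over the list alone. Tubulin and actin genes as a whole gave 5 of 9 higher (median 1.99, adjusted p = 1.4e-13), with ACT12 and TUA1 in both lists. APPB1 (4.90 ± 0.81), AT5G51950 (4.77 ± 0.56), AT1G23840 (4.45 ± 0.81) and AT2G40620 (3.73 ± 0.27) were also among the highest. AT1G23130 at -3.84 ± 0.52, AT4G28085 at -3.03 ± 0.95 and AT4G04460 at -2.87 ± 0.45 were lowest. The cold-inducible genes KIN1 and KIN2 were higher by 3.00 ± 0.52 and 2.93 ± 0.47, while AIM1, a gene of fatty acid β-oxidation, was higher by 1.58 ± 0.25. AT4G28085 missed the threshold without petal replicate 1 (adjusted p = 0.077) or 2 (0.075) and without sepal replicate 1 (0.12) or 2 (0.067). Uncentred, 56.2% of the calls were higher, against 69.5%.

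**Figure D2:**
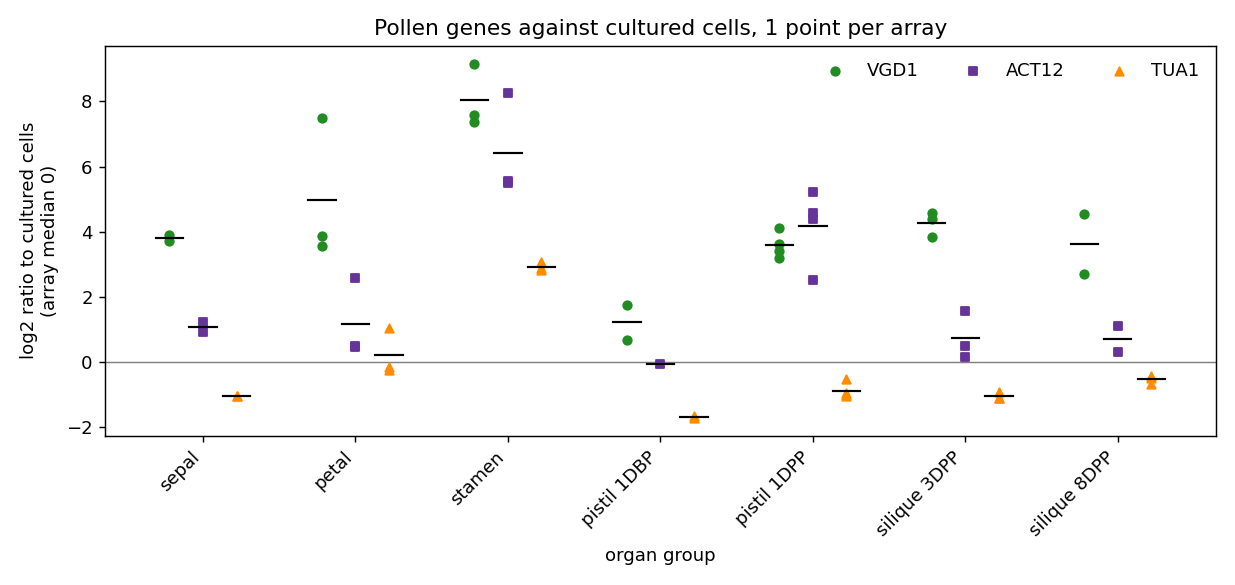
Log2 ratios to cultured cells of the pollen genes VGD1, ACT12 and TUA1 in flower organs and siliques, with 1 point per array and a black bar at each group mean. All 3 had their highest mean in stamens, at 8.03, 6.42 and 2.93.

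The 1DBP pistil differed from petals and sepals at 7695 of 22593 probes, 5092 higher and 2603 lower, the most among flower organs. THI2.1 was higher by 8.33 ± 0.87 (n = 2 against 5), ATLP-1 by 6.70 ± 0.83, AT1G62500 by 6.32 ± 1.22, the peroxidase gene AT1G44970 by 6.0 ± 0.82 and the histone H2B gene HTB2 by 5.15 ± 0.63. AT3G62550 lay at -7.40 ± 1.04, AT1G23130 at -7.21 ± 0.59, AT3G11930 at -6.04 ± 0.33 and the metallothionein gene MT1C at -5.33 ± 0.44. PRL and TOPII were higher by 4.72 ± 0.56 and 4.49 ± 0.55, and INO by 3.47 ± 0.43. The carpel regulator SPT was not called between these groups, though it lay above cultured cells in 1DBP pistils at 2.26 ± 0.51. The 3 chlorophyll synthesis genes were higher, PORB by 2.99 ± 0.91, GSA1 by 2.04 ± 0.38 and CHLM by 1.73 ± 0.35, 3 also when adjusted over the list alone, but the list test gave an adjusted p of 0.40. Peroxidases split 6 higher and 6 lower of 22. Without replicate 2 of the pistils AT1G62500 gave an adjusted p of 0.070, CHLM 0.066 and PORB 0.061, and without replicate 3 PORB gave 0.076. The count was 4719 without replicate 2. Uncentred, only 42.2% of the calls were higher, against 66.2%, so the direction of the balance turned.

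Between the 2 pistil stages 263 of 24433 probes were called, 189 higher and 74 lower in 1DPP pistils (n = 4 against 2). The count is no measure of how alike the stages were, as the fit recovered only 28 of 100 simulated log2 changes of 1.5 here. PSBY, a photosystem II gene, was higher by 6.43 ± 1.19 (adjusted p = 0.0065), APPB1 by 5.19 ± 0.96, AT4G15750 by 4.04 ± 0.92 and the peroxidase gene AT4G36430 by 3.73 ± 0.64. AT5G22430 lay at -4.01 ± 0.91 and AT2G19460 at -3.55 ± 0.90. The photosynthesis list moved upwards, with a median of 1.00 and an adjusted p of 2.6e-05 (0.00022 with an estimated correlation), though PSBY alone of its 8 genes was called, and 2 when adjusted over the list alone. Peroxidases also passed the list test (adjusted p = 0.0045, and adjusted p = 0.030 with an estimated correlation), with 2 higher and 1 lower of 22 and a median of 0.18. That test gave 0.077 without 1DBP replicate 2. ACT12 had a value on a single 1DBP array and was not tested here. It stood at 4.17 ± 1.16 (SD, n = 4) above cultured cells in 1DPP pistils, while VGD1 stood at 1.22 ± 0.75 (SD, n = 2) in 1DBP and 3.58 ± 0.40 (SD, n = 4) in 1DPP pistils. None of the 16 genes named by the rule kept its call whichever array was left out. The largest adjusted p was 0.19 for PSBY and AT4G15750 without 1DBP replicate 3, 0.12 for APPB1 and 0.15 for AT4G36430 without 1DBP replicate 2, 0.41 for AT5G22430 without 1DBP replicate 3, and 1.00 for AT2G19460 without 1DBP replicate 2. The count fell to 111 without 1DBP replicate 2, and uncentred calls were 90.9% higher, against 71.9%.

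The 3DPP silique differed from the 1DPP pistil at 729 of 25551 probes, 423 higher and 306 lower (n = 3 against 4). Peroxidase genes led both ends, with AT3G32980 higher by 5.40 ± 0.79 and AT1G44970 at -5.50 ± 0.74. AT4G15750 was higher by 4.09 ± 0.81 and AT5G05750 by 3.88 ± 0.98. ACT12 was lower in siliques, at -3.42 ± 0.72 (adjusted p = 0.0055), as were AT2G18690 at -3.07 ± 0.49, a bound since 1 of 3 silique values lay at the smallest deposited ratio, and, further down the list, the heat shock gene AT1G53540 at -2.63 ± 0.63. DNA recombination and repair genes passed the list test (adjusted p = 0.026, and adjusted p = 0.018 with an estimated correlation). The helicase genes RECQSIM and RECQ4B were lower, at -2.38 ± 0.59 and -2.20 ± 0.34, while ATSPO11-1 was higher by 2.08 ± 0.57. Chlorophyll synthesis genes had a median of 1.07 (adjusted p = 0.034, and adjusted p = 0.036 with an estimated correlation), with 0 of 3 called by limma and 2 when adjusted over the list alone. Photosynthesis genes had 0 calls by limma, though 3 of 7 when adjusted over the list alone. Without silique replicate 2 the repair and chlorophyll tests gave 0.18 and 0.059, and uncentred 0.066 and 0.063. The chlorophyll list also missed without silique replicate 1 (0.086) and pistil replicates 1 (0.060) and 4 (0.065), and the repair list without pistil replicate 4 (0.052). ATSPO11-1 gave an adjusted p of 0.055, 0.14, 0.078 and 0.050 without pistil replicates 1 to 4, and 0.056 without silique replicate 2. RECQSIM gave 0.13 without silique replicate 2, 0.058 without pistil replicate 2 and 0.057 without pistil replicate 4. AT1G53540 gave 0.054 and 0.073 without silique replicate 1 or 3. The count was 441, 445 and 443 without silique replicates 1, 2 and 3. Uncentred, 18.5% of the calls were higher, against 58.0%.

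The 8DPP silique differed from the 3DPP silique at 3207 of 21315 probes, 1689 higher and 1518 lower (n = 3 and 3). AT2G25625 was higher by 5.05 ± 0.61, GRX480, a glutaredoxin gene, by 4.32 ± 0.39, AT3G28670 by 4.30 ± 0.51 and PYK10, a β-glucosidase gene of endoplasmic reticulum bodies, by 4.27 ± 0.56. AT3G48200 lay at -5.82 ± 1.22, PORB, a protochlorophyllide oxidoreductase gene, at -5.71 ± 0.99 and AT1G48610 at -4.18 ± 0.70. The heat shock gene AT1G53540 was higher by 3.20 ± 0.75. No list passed its test, and of 22 peroxidases 3 were higher and 1 lower. Uncentred, 91.6% of 4837 calls were higher, against 52.7%. The count was 972 without 8DPP replicate 2 and 986 without replicate 1, and 936 for probes with a value on all 6 arrays.

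Among dark seedling organs, cotyledons differed from hypocotyls at 3697 of 23580 probes, 2331 higher and 1366 lower (n = 3 against 2). Photosynthesis genes rose together, with 6 of 7 higher, 6 also when adjusted over the list alone, a median of 4.25 and an adjusted p of 2.2e-06. AT1G75460 was the highest named gene, at 5.62 ± 1.27, followed by PSAE-1 at 5.29 ± 1.29, LHCB4.2 at 4.66 ± 1.37, LHB1B2 at 4.53 ± 0.63 and LHCB4.1 at 4.45 ± 0.40. PORB, CHLM and GSA1 were higher by 3.75 ± 0.99, 2.41 ± 0.38 and 1.29 ± 0.42 (adjusted p of the list 0.033, and adjusted p = 0.035 with an estimated correlation), 3 of 3 also when adjusted over the list alone. Peroxidases went the other way, with 11 of 23 lower and 2 higher (median -1.90, adjusted p = 9.9e-09), led by AT5G19890 at -4.64 ± 0.84 and AT2G37130 at -4.09 ± 0.63. AT1G27030 lay at -5.62 ± 0.73 and AT1G04560 at -5.14 ± 1.12. Without hypocotyl replicate 1 or 2 the adjusted p was 0.11 or 0.089 for LHCB4.2, 0.063 or 0.061 for PORB and 0.14 or 0.15 for GSA1. It was 0.080 for PSAE-1 without hypocotyl replicate 1 and 0.14 for GSA1 without cotyledon replicate 1, and the chlorophyll list missed without cotyledon replicate 3 (0.063). Centred on named probes, 51.5% of the calls were higher, against 63.1%. The count was 2039 without hypocotyl replicate 1 and 2077 without hypocotyl replicate 2.

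Dark roots differed from dark hypocotyls at 1572 of 22604 probes, 1162 higher and 410 lower. AT1G68850 was higher by 4.51 ± 0.86, AT5G38070 by 4.32 ± 1.34 and AT5G24870 by 4.31 ± 1.08, and AT1G28660 was lowest, at -4.31 ± 1.15. Of 22 peroxidases 8 were higher and none lower, but the list gave an adjusted p of 0.19. The calls are fragile: 11 of 16 named genes missed the threshold without some array, among them AT5G38070 without root replicate 2 (adjusted p = 0.63) or hypocotyl replicates 1 (0.18) and 2 (0.17), AT5G24870 without root replicate 2 (0.10) or hypocotyl replicates 1 (0.056) and 2 (0.12), and AT1G28660 without hypocotyl replicate 1 (0.26) or root replicates 1 (0.087) and 2 (0.086). The count was 647 and 662 without hypocotyl replicates 1 and 2 and 916 and 911 without root replicates 1 and 2, and 60.8% of the calls were higher when centred on named probes, against 73.9%. Light cotyledons differed from light hypocotyls at 4294 of 14564 probes, 1135 higher and 3159 lower, around a median of -0.38. The light hypocotyl arrays hold fewer values than most, and each array was centred on the values it holds. Probes tested between light and dark hypocotyls had a median of -0.35 in light cotyledons. Missing values may thus account for much of the shift and of the lower calls, which cannot be told apart from a difference between organs. AT2G41090 was higher by 7.45 ± 0.89, AT1G32470 by 5.98 ± 1.12 and AT1G65190 by 4.96 ± 0.94, while AT2G37130 lay at -7.59 ± 0.69, OSM34 at -5.73 ± 0.45 and AT5G64100 at -5.33 ± 0.63. Peroxidases were again lower as a group, 7 of 13 against 2 higher (adjusted p = 0.0019). Of 3 measured photosynthesis genes 2 were higher, and 3 when adjusted over the list alone (adjusted p = 0.0019). Uncentred, 9.64% of the calls were higher, against 26.4%.

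Germinating seeds differed from the mean of the 3 dark seedling organs at 8472 of 20097 probes, 3704 higher and 4768 lower (n = 3 against 7). MCCA was higher by 6.03 ± 0.30, AT1G23780 by 4.48 ± 0.61, AT2G16365 by 3.98 ± 0.47 and AT4G13360 by 3.73 ± 0.35. NRPB7, an RNA polymerase II subunit gene, was higher by 3.30 ± 0.38. AT1G05340 lay at -7.67 ± 0.33, with both seed values at the smallest deposited ratio, AT2G18690 at -7.35 ± 0.45, AT1G32920 at -6.53 ± 0.28 and AT2G37130 at -6.44 ± 0.48. Of 21 peroxidases 12 were lower and none higher (adjusted p of the list 0.15). The β-glucosidase gene BGLU40 lay at -5.22 ± 0.40, the transferase genes GSTF4 and UGT71C4 at -3.75 ± 0.41 and -3.49 ± 0.27, AIM1 at -1.29 ± 0.24 and TOPII at -1.51 ± 0.45. Of 13 ubiquitin protease and conjugating enzyme genes 5 were lower and 2 higher, and no list passed its test. Uncentred, 66.5% of the calls were higher, against 43.7%, which turned the balance.

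The light comparisons ask which genes differ between an organ in light and the same organ in the dark. On the direct cotyledon arrays 2946 of 25907 probes were called, 1698 higher and 1248 lower in light (n = 2). Light was in channel 1 on both arrays, so dye and light are confounded in these calls. AT1G23130 was higher by 4.87 ± 0.50, the glycosyltransferase gene UGT76E12 by 4.80 ± 0.77, AT4G27560 by 4.72 ± 0.73 and AT5G38980 by 4.65 ± 0.95. AT4G27450 lay at -5.43 ± 0.30, the peroxidase gene AT2G37130 at -5.19 ± 0.49, AT5G46900 at -5.00 ± 0.50, AT1G19530 at -4.82 ± 0.26, the oleosin gene OLEO3 at -4.44 ± 0.71 and SPT at -3.84 ± 0.51. Photosynthesis genes moved as a group, with 5 of 8 called, 7 when adjusted over the list alone, a median of 2.40 and an adjusted p of 6.5e-05. Since light over dark was read from these genes, their sign here is not a finding. PSAN was higher by 2.95 ± 0.30, LHCB4.3 by 2.93 ± 0.39 and LHB1B2 by 2.60 ± 0.49. Of 23 peroxidases 6 were lower and 1 higher (adjusted p = 0.00096). Both glucosinolate genes measured were higher, UGT74B1 by 2.26 ± 0.36 and BCAT4 by 1.68 ± 0.48. Without replicate 1, AT5G38980 gave an adjusted p of 0.071 and LHB1B2 0.054. The count was 1607 and 1765 on a single array with the spread taken from the other groups, and limma on the 2 arrays alone called 0 probes, with 7010 at an unadjusted p under 0.05. Centred on named probes 41.4%, and uncentred 43.5%, of the calls were higher, against 57.6%.

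Through the reference, light and dark cotyledons differed at 2045 of 25314 probes, 1242 higher and 803 lower (n = 2 against 3). AT4G27560 was higher by 6.12 ± 0.95, UGT76E12 by 6.06 ± 1.09, AT1G23130 by 5.49 ± 0.64 and PSAN by 4.26 ± 0.38, and AT2G37130 lay at -6.48 ± 0.63. Of the photosynthesis genes 3 of 8 were higher, 3 also when adjusted over the list alone (median 1.70, adjusted p = 0.0017). Of 24 peroxidases 5 were lower and 1 higher (adjusted p = 0.0038). These were separate hybridizations from the direct ones, though the labels do not say that the RNA was separate, and their log2 changes correlated at 0.54 across probes, which are not independent replicates. Of the probes tested both ways 912 were higher in both, where independent lists would share 84.6, and 436 were lower in both, against 37.6. The count was 1068 without light cotyledon replicate 1 and 1128 without replicate 2.

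On the direct root arrays 2278 of 24974 probes were called, 1202 higher and 1076 lower in light (n = 2). The cold-inducible genes KIN2 and KIN1 were higher by 4.81 ± 0.45 and 4.24 ± 0.50, AT1G13930 by 4.54 ± 0.52, AT3G57020 by 4.42 ± 0.35 and EXPB3 by 4.06 ± 0.77. LHB1B2 was higher by 2.72 ± 0.49. AT1G09310 lay at -4.67 ± 0.42, AT1G19530 at -4.08 ± 0.26 and AT1G04560 at -3.70 ± 0.87. No list passed its test. Of the photosynthesis genes LHB1B2 alone was called. Through the reference 1479 of 23808 probes were called, 1223 higher and 256 lower, around a median of 0.24. AT3G57020 was higher by 5.82 ± 0.50, KIN2 by 5.01 ± 0.64 and KIN1 by 4.28 ± 0.71, and AT1G09310 lay at -5.60 ± 0.59, CLE43 at -4.71 ± 1.02 and AT1G19530 at -4.56 ± 0.37. The 2 measurements correlated at 0.49, and shared 638 higher probes, against 63.0 for independent lists, and 111 lower ones, against 9.25. Dye does not cancel through the reference here, as light root replicate p1 had the organ in channel 1 and both dark root arrays in channel 2. The direct root arrays also had light in channel 1, and correlated at -0.35 with the dye difference between the light root arrays. A dye effect may thus add to the overlap and to the higher share, and cannot be told apart from a light response. Without direct replicate 2 the direct count fell to 475, and EXPB3 gave an adjusted p of 0.096 and AT1G04560 0.38. CLE43 gave 0.31 without light root replicate p1, without which the count through the reference fell to 228. That count was 382 without dark root replicate 2 and 2233 without light root replicate n1. Scaling between arrays moved that count to 2665 and leaving out centring to 574, with 54.5% higher in place of 82.7%. On the direct arrays the higher share was 34.4% uncentred and 34.5% centred on named probes, against 52.8%, and 21.8% of 1805 calls in a fit on these arrays alone.

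For hypocotyls the 2 measurements did not go together, and the direction of the direct arrays is not settled. As deposited, 4166 of 24882 probes were called on the direct arrays, 2398 of one sign and 1768 of the other (n = 2). The largest sizes with positive sign were AT1G19530 at 5.72 ± 0.26, AT5G46900 at 5.44 ± 0.50, AT3G15450 at 5.10 ± 0.28 and AT2G37130 at 5.04 ± 0.49. With negative sign they were AT1G65190 at -4.41 ± 0.67, LHB1B2 at -4.33 ± 0.49, AT4G27560 at -4.19 ± 0.73 and FLR1 at -3.73 ± 0.62. Photosynthesis genes had a median of -1.93, with 5 of 8 called negative (adjusted p = 0.00083), 5 also when adjusted over the list alone, and KIN2 and KIN1 lay at -3.55 ± 0.45 and -3.37 ± 0.50. Peroxidases had 8 of 23 positive (adjusted p = 0.032, but adjusted p = 0.13 with an estimated correlation, and 0.063 without replicate 2). Limma on the 2 arrays alone called 0 probes, with 8435 at an unadjusted p under 0.05, while leaving out replicate 1 gave 2091 calls. Uncentred 16.7% of the calls were positive, against 57.6%. Through the reference 5248 of 14017 probes were called, 4318 higher and 930 lower in light, around a median of 0.65 (n = 2 and 2). The heat shock gene AT1G53540 was higher by 4.95 ± 0.83, AT1G69680 by 4.92 ± 0.64 and AT5G58370 by 4.64 ± 0.51. AT1G28660 lay at -6.41 ± 1.15, AT5G10580 at -5.93 ± 0.87, AT5G48290 at -5.44 ± 0.99 and the β-glucosidase gene BGLU21 at -4.45 ± 0.92. Of 3 photosynthesis genes 2 were higher, 2 also when adjusted over the list alone (median 3.12, adjusted p = 0.040, but adjusted p = 0.051 with an estimated correlation), and that test missed the threshold without light replicate 1 (0.10) or 2 (0.10), without dark replicate 2 (0.073), uncentred (0.089) and with scaling between arrays (0.064). Of 12 ubiquitin protease and conjugating enzyme genes 8 were higher and 1 lower. The β-glucosidase list was lower (median -2.32, adjusted p = 0.040), with 2 of 3 called, and missed the threshold without light replicate 1 (0.10) or dark replicate 2 (0.074). Across probes the direct and reference values correlated at -0.08. They shared 260 positive calls, against 585 for independent lists, and 213 and 353 probes were called positive and negative on the direct arrays but the other way through the reference.

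**Figure D3:**
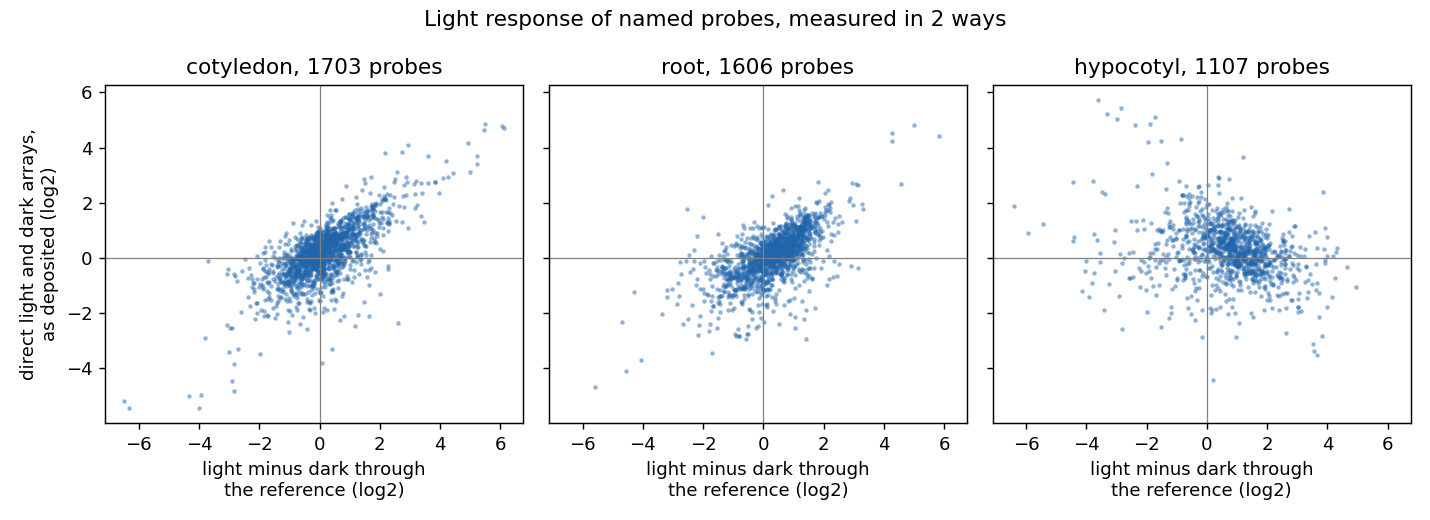
Log2 ratio of the direct light and dark arrays as deposited (vertical) against the light minus dark difference through the cultured cell reference (horizontal) for probes with a gene name, with 1 point per probe. Over all probes the 2 measurements correlated at 0.54 in cotyledons, 0.49 in roots and -0.08 in hypocotyls.

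The light response itself was compared between organs. On the direct arrays cotyledons and roots differed at 1481 of 24204 probes, 766 with a higher and 715 with a lower response in cotyledons. AT1G23130 (5.39 ± 0.70) and AT1G09310 (5.34 ± 0.59), the second through a fall in roots, were higher, and AT2G37130 at -6.26 ± 0.69 and AT5G46900 at -5.53 ± 0.70 lower. Photosynthesis genes responded more in cotyledons, with 3 of 8 called, 5 when adjusted over the list alone (median 1.86, adjusted p = 0.0017), and KIN2 and KIN1 more in roots, at -3.48 ± 0.64 and -3.15 ± 0.71. Peroxidases had a median of -1.02 (adjusted p = 0.013, but adjusted p = 0.065 with an estimated correlation), and that test gave 0.18 without root replicate 2. KIN1 gave an adjusted p of 0.12 without cotyledon replicate 2 and 0.071 without root replicate 2. The count was 680 without root replicate 2 and 896 and 761 without cotyledon replicates 1 and 2. Cotyledons and roots shared 281 higher calls, against 83.0 for independent lists, and 111 lower ones, against 48.8. Both had light in channel 1 on all direct arrays, and correlated at -0.21 and -0.35 with the dye difference between the light root arrays. A shared dye effect may thus add to this overlap and cannot be told apart from a shared light response. Through the reference cotyledons and hypocotyls differed at 3777 of 13697 probes, 557 higher and 3220 lower around a median of -0.67, which goes with the median of 0.65 in hypocotyls. AT1G28660 (6.01 ± 1.56) and AT5G10580 (5.72 ± 1.24), which fell in hypocotyls, were highest, and AT5G58370 at -5.83 ± 0.70 and AT1G69680 at -5.46 ± 0.86 lowest. That count was 2511 without light cotyledon replicate 2.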

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

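Of the tests here, those on the direct hypocotyl arrays, on missing values and on stamen RNA were chosen after the result was seen, while the test on levels in other organs was not.

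The light responses of organs differed by a test of the difference itself. Between cotyledons and roots on the direct arrays 1481 probes differed. As cotyledon minus root, the differences were AT1G23130 (5.39), AT1G09310 (5.34), UGT76E12 (5.09), AT5G38980 (4.95), AT2G37130 (-6.26), AT5G46900 (-5.53), GSTU26 (-4.17) and OLEO3 (-4.09). That of AT1G09310 came mostly from a fall in roots (-4.67). Between cotyledons and hypocotyls through the reference 3777 differed, 3220 of them lower around a median of -0.67. That median goes with the shift of light hypocotyls weighed below, so this count is not a measure of the light response alone. As cotyledon minus hypocotyl, they were AT1G28660 (6.01), AT5G10580 (5.72), AT2G42060 (5.22), AT1G65190 (5.02), AT5G58370 (-5.83), AT1G69680 (-5.46), TBL39 (-5.08) and AT5G24870 (-4.93). AT1G28660 and AT5G10580 fell in hypocotyls (-6.41 and -5.93) and moved little in cotyledons (-0.40 and -0.22), while AT1G65190 rose in cotyledons (5.22). On the direct arrays AT5G38980 missed the threshold without cotyledon replicate 1 (adjusted p = 0.18) or 2 (0.069) and root replicate 1 (0.054) or 2 (0.18), OLEO3 without cotyledon replicate 2 (0.18) or root replicate 1 (0.12), and UGT76E12 without cotyledon replicate 2 (0.10) or root replicate 2 (0.068). Through the reference AT2G42060 missed it without dark hypocotyl replicate 2 (0.087), and AT5G24870 without that array (0.063) or light hypocotyl replicate 2 (0.088). The counts were 680 without root replicate 2, 896 and 761 without cotyledon replicates 1 and 2, and 2511 without light cotyledon replicate 2. No single array stood out in the only group of 4, the 1DPP pistils.

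The direct hypocotyl values mostly opposed the other light comparisons. Among 141 probes called the same way in direct cotyledons and roots, and also called on the direct hypocotyl arrays, 93.6% had the opposite sign there. The arrays through the reference argue in part against an opposite answer of hypocotyls to light. Of the 179 probes called the same way in direct cotyledons and roots and called for hypocotyls through the reference, 5.59% had the opposite sign. Some agreement in sign is built in, as 82.3% of all hypocotyl calls through the reference were higher. Direct cotyledons and roots likewise shared 281 higher calls and 111 lower ones, an overlap to which a shared dye effect may add. The direct hypocotyl arrays had light in channel 2, and the direct cotyledon and root arrays in channel 1. The dye difference between the light root arrays was taken out with either sign, and the correlation with the reference values larger in size was -0.19. That difference rests on a single array of each orientation, so it does not decide on a dye effect. The values may run dark over light on the 2 direct hypocotyl arrays, a hypothesis found and tested on the same data. Of the probes called higher on the direct cotyledon arrays 52 had the same sign on the direct hypocotyl arrays, against 164 for independent lists, and 436 the opposite one. For those called lower it was 59, against 81.4, and 405. For roots it was 56, against 121, and 174 among the higher, and 99, against 64.4, and 109 among the lower, so the opposition was not uniform. Over all probes the direct and reference values correlated at -0.08 in hypocotyls, 0.54 in cotyledons and 0.49 in roots. After centring, the median of named probes was 0.12 and 0.11 on the direct hypocotyl arrays. It was positive on all other arrays read as channel 1 over channel 2, and negative on those with the organ in channel 2. The direct values correlated with the dye difference at -0.26 in hypocotyls, -0.21 in cotyledons and -0.35 in roots. With light in channel 2, light over dark would turn both signs under a dye effect, so these values argue against it. Organ and channel are confounded, so the direction is not settled.

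Light hypocotyls lay mostly above dark ones through the reference, by a median of 0.65 over the 14017 probes tested. These arrays hold fewer values than most, and the probes they do hold had a median of -0.50 in dark hypocotyls, below 0 but by less than 0.65, so missing values may account for part of the shift and cannot be told apart from a change in light. The same probes had a median under -0.1 in 14 of 15 other organ groups, which is consistent with a set of probes low in organs generally. A response of hypocotyls to light stays open, untested.

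Single pollen genes were also high outside stamens, though the list of 3 passed no test there. VGD1 stood at 4.96 in petals and 3.81 in sepals, against 8.03 in stamens, and ACT12 at 1.19 and 1.08. Stamen RNA carried over would lower VGD1 and ACT12 alike, and ACT12 lay further below its stamen level than VGD1 by 2.16 ± 1.16 in petals and 1.12 ± 1.29 in sepals, so carry-over cannot be told apart from expression in these organs, as the errors are wide. TUA1 lay above the ACT12 distance by 2.53 ± 0.82 in petals and 1.38 ± 0.92 in sepals, which argues against carry-over as the whole source of TUA1 in petals. TUA1 stood at 0.22 in petals and 0.12 in rosette leaves, however, so this does not settle VGD1. Probes higher in stamens changed by a median 0.196 more than others between 1DBP and 1DPP pistils, and 75 of 1155 were called higher there (6.49%), against 105 of 21224 (0.495%). That median falls just short of a bound of 0.2, which was set after the result was seen and so decides nothing. Stamen RNA in the 1DPP pistils may add to the median and to the calls but is not settled, and expression in pistils was not tested. In 1DPP pistils ACT12 lay at -2.25 ± 0.72 and VGD1 at -4.45 ± 0.81 against stamens, so the order of petals and sepals turned. Equal carry-over of both would leave no gap, and the gap was -2.20 ± 1.08, and -1.55 ± 0.77 between TUA1 and ACT12. Both are barely past 2 standard errors, rest on the same ACT12 value and were chosen after they were seen, so they do not settle this.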

How the results depend on the processing

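Centring on named probes and turning the direct hypocotyl arrays in the combined fit were chosen after seeing the data; the other settings were not. Of 9137 values of named genes under these settings 8268 kept their direction and call, 868 kept the direction alone and 1 turned: AT2G18980 through the reference in hypocotyls, at -0.15 without light hypocotyl replicate 1 and 3.30 without replicate 2. The losses among gene values were uneven. In the fit on the groups compared alone 170 lost the call and 161 kept it, and with the array number as a block 216 lost it and 96 kept it. For probes with a value on every array compared 984 kept it and 0 lost it, as p-values there were only adjusted anew. Of 525 list values 495 kept the call and 30 the direction alone. Without some array 42 of 649 calls of named genes against cultured cells were lost, and 147 of 438 in the other comparisons, a gene counting once per comparison. A lone array left in a group is assumed to vary like the other groups. Turning the hypocotyl arrays changes signs by construction. No centring gave 4837 calls between siliques and 574 for roots through the reference. Scaling gave 807 for petals against sepals, 907 for dark roots against dark hypocotyls and 2665 for roots through the reference, and the channel 2 light root array alone gave 228. Probes with a value on every array gave 2700 for 8DPP siliques against cultured cells and 936 between siliques, as fewer were tested. Over all comparisons the median of tested probes lay between -1.15 and 1.12 uncentred, -0.60 and 0.56 scaled, and -0.52 and 0.46 centred on named probes. Fitting the groups alone, with fewer arrays to estimate the spread, limma gave 0 calls for direct cotyledons (7010 at an unadjusted p under 0.05), direct hypocotyls (8435), petals against sepals (4651), dark roots against dark hypocotyls (4868) and light cotyledons against light hypocotyls (4636), 8 for cauline against rosette leaves, 33 between pistils, 441 for 3DPP siliques against 1DPP pistils and 315 between siliques.

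Leaving out 1 array gave 660 to 1550 calls for cauline against rosette leaves, 2039 to 3254 for dark cotyledons against dark hypocotyls, 636 to 2027 for petals against sepals, 4719 to 7956 for 1DBP pistils against petals and sepals, 111 to 328 between pistils, 441 to 732 for 3DPP siliques against 1DPP pistils, 972 to 3133 between siliques, 2790 to 8024 for 8DPP siliques against cultured cells and 647 to 916 for dark roots against dark hypocotyls. For light it gave 1607 to 1765 in direct cotyledons, 2091 to 3072 in direct hypocotyls, 475 to 2772 in direct roots, 1068 to 1833 for cotyledons and 228 to 2233 for roots through the reference, 680 to 1603 between the responses of cotyledons and roots and 2511 to 3991 between those of cotyledons and hypocotyls. Where not stated, the cause was not tested.

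For arrays of the same number, correlations in the pairing check ran from -0.123 to 0.25. Values over 0.1 were found for 3 of 7 pairs in stamens against petals and sepals. They were also found for 1 of 3 in cauline against rosette leaves and 1 of 9 in stem against leaves. These cannot be correlations of the array values, whose lowest between any arrays against cultured cells was 0.295. Deviations from group means are their likely basis. In the smallest groups such deviations mirror each other, so pairs there are not separate and the check has little power. A pairing by number was thus neither shown nor excluded. With the number as a replicate block in a fit on the groups alone, limma gave 0 calls for cauline against rosette leaves (3208 at an unadjusted p under 0.05), petals against sepals (8223), pistils (2142), 3DPP siliques against 1DPP pistils (3679), siliques (3658), dark roots (4831), dark cotyledons (5474) and light cotyledons (3657) against hypocotyls, and cotyledons (3995) and hypocotyls (4657) through the reference. It gave 3508 for 1DBP pistils and 1851 for stamens against petals and sepals, 1202 of these among the 1757 calls without it. No block was fitted for roots through the reference, as the light arrays, both numbered 1 in their labels, were entered as n1 and p1.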

Other observations

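The tests here, other splits of the arrays, were planned before the result was seen.

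Splits of the arrays were counted for the 4 comparisons with at least 3 arrays in each group. As the replicates may be technical, these splits do not speak to variation between plants. For stem against leaves 1 of 100 splits, the real one with 4192 calls, gave as many. The highest other gave 4070 with the 3 stem arrays kept together, a split that leaves the stem difference in place. Splits that mixed stem and leaf arrays gave 1712 at most. For 3DPP siliques against 1DPP pistils it was 1 of 35, with 729 calls and 261 at most in another. For cauline against rosette leaves (1 of 10, 1056 and 52) and 8DPP against 3DPP siliques (1 of 10, 3207 and 609) the splits are too few for a share under 0.05.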
